A study of Mus musculus with 2 samples.

How the data were processed

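Small RNA sequencing was carried out on total RNA from tissue labelled as a layer of hippocampus, of female B6CASTF1/J mice of 18 to 20 months, with a size limit of 30 nt, per the labels. A multiplexed miRNA library protocol is cited in the labels. The 2 libraries are numbered as biological replicates 1 and 2 in the labels. The tissue records differ in animal number but name the same donor record, so separate animals are likely from the labels but are not certain, and differences between the libraries may be partly technical. Both belong to 1 group, with no second condition.

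The deposited files hold raw counts per miRNA gene, 1 file per library, not pooled. They list each gene without strand, on the sense strand and on the antisense strand, after 4 rows of totals for unmapped, multimapping, unassigned and ambiguous reads. The assembly was mm10 and the annotation GENCODE M21, per the README files deposited with the counts. The aligner, the counter and their settings are not given in the sources used here. All 2202 genes were named from the GENCODE M21 annotation, which also gave positions, strands, host genes and hairpin sequences. The 4 rows of totals were kept out of library sizes and tests. In replicate 1, of 7481717 reads, 30.2% were sense counts in miRNA genes, 29.0% were unmapped, 36.2% were multimapping and 4.68% fell in no annotated gene. In replicate 2, of 12159538 reads, these shares were 37.2%, 11.2%, 47.9% and 3.72%.

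That processing shapes the levels. Reads that fit several genomic places are a separate total in the deposited counts, so genes with identical copies can lose reads. Genes are hairpins, so the counted reads of both mature arms are summed. In the unstranded column, genes that overlap a miRNA gene on the other strand lose reads: Mir126a, Mirlet7e and Mir191 read 0 there, and Mir219a-2 fell to 0.241 CPM. The sense column was used as the main one. The reference genome is that of the B6 parent, so CAST alleles that differ from it could lose reads, equally in both libraries.

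Sense counts were divided by the library's sum and multiplied to CPM. Means and SDs are over both libraries, and intervals for single libraries are exact 95% Poisson intervals. A count of 0 allows up to 3 counts. Ligation and PCR make reads that are not independent molecules, so intervals and floors cover counting error only. Log2 CPM values used a pseudocount of 1 CPM, and log2 ratios between the libraries a pseudocount of 0.5 counts. Agreement was measured by Pearson's r and Spearman's rho across genes at 1 CPM or more in either library, by chi-square against Poisson sampling and by the common dispersion of edgeR's estimateDisp with an intercept only and TMM factors, with an interval from 100 bootstrap draws of genes.

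Genes with a mean of 1 CPM or more were compared by a two-sided exact conditional binomial test with Benjamini-Hochberg adjustment and called at adjusted p under 0.05 and 2-fold or more. With 1 library per tissue sample no replicated test is possible: even with 2 values against 2, an exact permutation test cannot go below 0.333. The median log2 ratio of each list was given as a percentile among 10000 random lists of the same size drawn within 10 expression classes. The neuron-enriched and other-tissue lists were compared by a two-sided permutation test with 100000 resamples.

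The 18 gene lists, the tests, most alternatives and the rule for named genes were written before the data were examined. The rule took the 20 genes of highest mean CPM; up to 4 members of highest mean CPM per list, and every member of lists of 6 or fewer; the 10 called genes of largest log2 ratio in each direction with a mean of 10 CPM or more; and the 5 genes with the most antisense counts among those with more antisense than sense counts. Genes named outside that rule were chosen after their values were seen. The listed genes Mir486b, Mirlet7j, Mirlet7k, Mir297a-1 and Mir466a had no match by name in the files. The bound of the central 95% of random lists was set after the medians were seen.

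The calls were tested on simulated data: counts for the real genes, drawn with the real library sizes, with 200 genes changed. The draws held Poisson counting error only, whereas the real libraries differed far more (chi-square over degrees of freedom 572). The shares of genes called below thus cover counting error and scaling only, and give no rate of false calls for the real libraries. In a first simulation the changed genes were drawn from all genes at 1 CPM or more, and 46% of the 2.5-fold and 88% of the 4-fold changes were called, with 4.15% of the unchanged genes. Of the changed genes at 10 CPM or more, 54.7% of the 2.5-fold and 100% of the 4-fold changes were called. The recovery of 2.5-fold changes was poor because changes in abundant genes shifted the totals, so that unchanged genes moved by -0.57 log2 units. A second simulation, made after that outcome, left the 20 most abundant genes unchanged. It called 73% and 85% of the changes, 96.7% and 100% of those at 10 CPM or more, and 0.676% of the unchanged genes. Scaling on library totals is thus sensitive to changes in a few abundant miRNAs. TMM factors and DESeq2 size factors were used for comparison, as set before the data were examined. Of 50 simulated lists of 12 genes shifted down by 1 log2 unit, 94% fell under the 2.5th percentile, and of 50 unshifted lists 4% fell outside the central 95%. The genes of these lists were drawn at random, like the lists they were set against, so the share of unshifted lists followed from the bound. Lists of clustered genes were not simulated.

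Alternatives were other filters, pseudocounts, scalings, a 1.5-fold threshold, the unstranded column, each library alone, and edgeR's exactTest with the dispersion of both libraries taken as 1 group. A correction for hairpin GC, the removal of same-named copies and the removal of each list's most changed member were added after the data were seen. For a test of the first base of mature miRNAs, the starts of 79 miRNAs were written from general knowledge after the ratios were seen, and each was checked to lie in its annotated hairpin. Whether it belongs to the dominant arm was not checked, and the counts sum both arms. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.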

Results

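MicroRNAs, short RNAs that silence matching messenger RNAs, were sequenced from hippocampal tissue of female B6CASTF1/J mice aged 18 to 20 months. B6CASTF1/J mice are first-generation hybrids of a laboratory B6 mother and a wild-derived CAST father. The series held 2 libraries of RNA shorter than 30 nt, labelled biological replicates 1 and 2, and they formed 1 group. No treatment, age or sex was contrasted, so the files describe a miRNA profile of aged hippocampal tissue and how far the libraries differed. The label gives the tissue as a layer of hippocampus, without saying which layer or how it was dissected, so the levels may not hold for the whole hippocampus. Replicate 1 held 2255838 sense-strand counts in miRNA genes, and replicate 2 held 4521208. A count of 0 allowed a level of up to 1.33 CPM (counts scaled to a library total of 1000000) in replicate 1 and 0.664 CPM in replicate 2, which covers counting error only. Values below are means ± SD over both libraries (n = 2) unless a library is named. Gene positions refer to the mm10 genome.

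In this tissue a few genes, let-7 genes foremost, held most of the miRNA counts. Multimapping reads, 1.20 per counted read in replicate 1 and 1.29 in replicate 2, are in none of the levels, ranks or shares below. These describe only the reads counted at a gene, and miRNAs with identical copies can be missing from the top ranks. Adapter ligation can also favour some miRNAs over others, which was not measured. Ranks, shares and ratios between genes are therefore those of reads, not of molecules. Mirlet7g was the most abundant gene, at 120699 ± 33219 CPM (SD, n = 2), followed by Mirlet7b at 75005 ± 9879 CPM, Mir139 at 72843 ± 3254 CPM and Mirlet7i at 58794 ± 3263 CPM. The let-7 family, which restrains growth and stem cell genes in differentiated tissue, took 32.3% ± 3.83 (SD, n = 2) of all counts. Mir744 stood at 37076 ± 1206 CPM, Mir127 at 35995 ± 6023 CPM, Mir99a at 35741 ± 20691 CPM, Mirlet7d at 31918 ± 13489 CPM and Mir132 at 28639 ± 14580 CPM. Mir126a, an endothelial miRNA, completed the top 10 at 25458 ± 5046 CPM. All 10 were in the top 10 of replicate 1 but 7 were in that of replicate 2, where Mir29a (31007 CPM), Mirlet7e (26944 CPM) and Mir23b (22843 CPM) stood above Mirlet7d (22380 CPM), Mir99a (21110 CPM) and Mir132 (18329 CPM). Those 10 genes held 52.2% of the counts and the top 20 held 67.7%. Of 2202 annotated miRNA genes, 446 reached 1 CPM in both libraries, 300 reached 10 CPM in both, and 1468 had no count in either library. Of the next 10 genes, Mir29a was at 23783 ± 10218 CPM, Mirlet7e at 23574 ± 4767 CPM, Mir23b at 19977 ± 4053 CPM and Mir191 at 14691 ± 1466 CPM. Mir125a, Mir128-1, Mir328, Mir151, Mir26b and Mir137 lay between 11037 and 12923 CPM. A count in these files belongs to a hairpin gene, so the mature arms of a hairpin were not told apart.

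**Figure D1:**
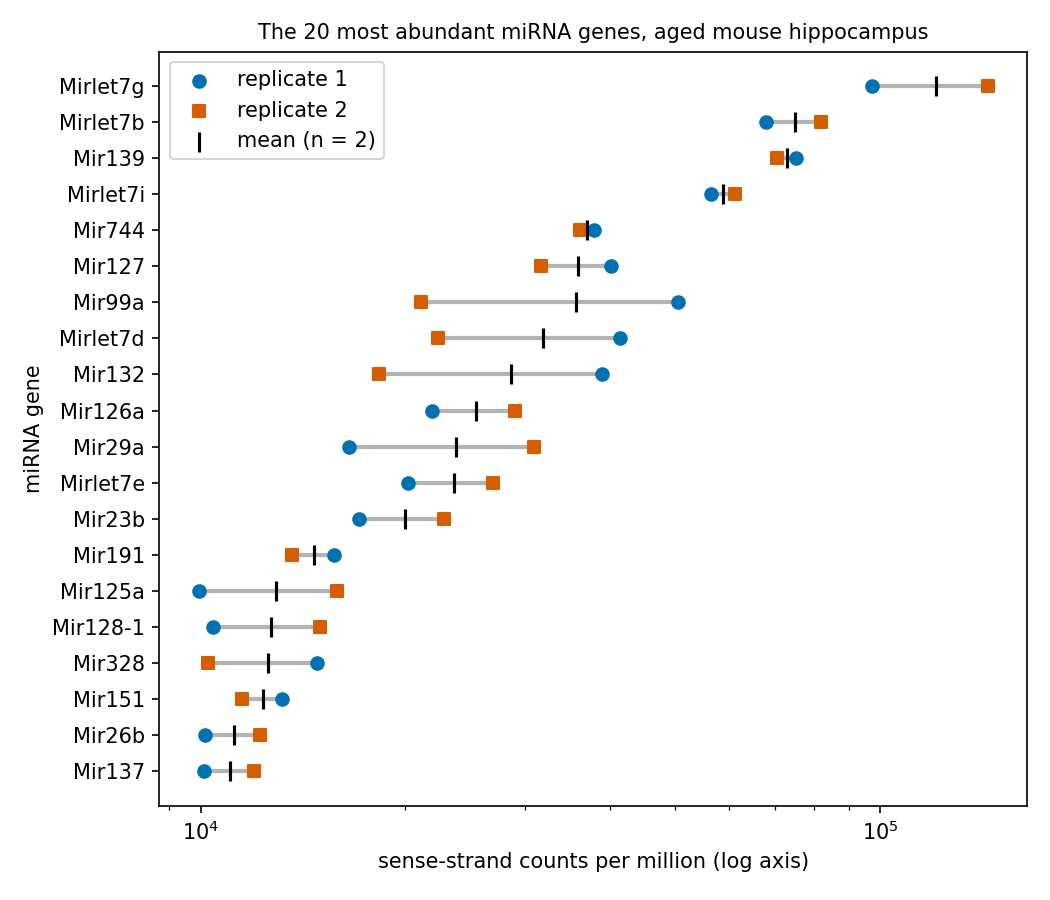
Sense-strand CPM (x axis, log scale) of the 20 most abundant miRNA genes (y axis) in replicate 1 (circles) and replicate 2 (squares), with the mean as a vertical tick and a grey line joining the libraries. Mirlet7g led in both libraries, and Mir99a and Mir132 were more than 2-fold lower in replicate 2.

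The most abundant genes lay mostly inside other transcripts. Here and below, a hairpin is placed in an exon if it overlaps an exon of any annotated transcript of its host gene. It can be intronic in the other transcripts of that gene. Mirlet7g (ENSMUSG00000065440.1) lies at chromosome 9, 106178840 to 106178927, in an intron of Wdr82. Mirlet7b (ENSMUSG00000065564.1) lies at chromosome 15, 85707319 to 85707403, in an exon of the noncoding transcript Lncppara. Mir139 (ENSMUSG00000065446.1) lies at chromosome 7, 101475376 to 101475443, in an intron of Pde2a, which encodes a cyclic nucleotide phosphodiesterase. Mir744 (ENSMUSG00000076460.1) lies at chromosome 11, 65734733 to 65734832, in an intron of Map2k4. Mir99a (ENSMUSG00000065530.1) lies at chromosome 16, 77598936 to 77599000, in an intron of Mir99ahg. Mir132 (ENSMUSG00000065537.2) lies at chromosome 11, 75173682 to 75173747, in an intron of the noncoding gene 1700016P03Rik. Mir126a (ENSMUSG00000065540.1) lies at chromosome 2, 26591357 to 26591429, in Egfl7, a gene of endothelial cells. It overlaps an exon of an annotated Egfl7 transcript.

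Neuron-enriched miRNAs were abundant and miRNAs typical of other organs were scarce. The 30 genes of the neuron-enriched list took 13.5% ± 1.79 of the counts, and 27 of them reached 1 CPM in both libraries. They were led by Mir127, Mir132, Mir128-1 and Mir137, the last at 11037 ± 1318 CPM. The other-tissue list, with miRNAs of muscle, liver, pancreas, gut, pluripotent cells and testis, took 0.0572% ± 0.0194, and 19 of its 39 genes had no count. Its highest member was Mir375, a miRNA of endocrine cells, at 461 ± 215 CPM. Mir122, the main miRNA of liver, was at 28.9 ± 20.2 CPM, Mir194-2 at 24.7 ± 0.193 CPM and Mir192 at 23.0 ± 4.42 CPM. The neuron-enriched genes lay 8.58 log2 units above the other-tissue genes in mean log2(CPM + 1). A two-sided permutation test across genes gave p = 1e-05, the smallest that 100000 resamples can give; genes are not independent replicates.

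Activity- and synapse-linked miRNAs, 18 genes that overlap the neuron-enriched list, took 4.97% ± 1.52 of the counts. Mir132, which responds to neuronal activity, led them. Mir138-1, known for its action at dendritic spines, was at 2994 ± 860 CPM, and Mir485 was at 2519 ± 573 CPM. All 12 genes described in brain ageing or senescence reached 1 CPM in both libraries, and they took 4.34% ± 1.25 of the counts. Mir29a led that list, followed by Mir22 at 10890 ± 3592 CPM, Mir21a at 3912 ± 2783 CPM and Mir29c at 3116 ± 1364 CPM. No young animals were in the series, so these levels have no age contrast.

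The glial, vascular and immune lists, each shorter than the neuron-enriched list, took lower shares of the counts. The lists differ in size and in the reads they can lose to multimapping, so these shares do not rank cell types. The neural progenitor and astrocyte-enriched list took 4.24% ± 1.503 of the counts, led by Mir29a and Mir125a. In that list, Mir29c followed, and Mir31 was at 821 ± 494 CPM. The oligodendrocyte-enriched list took 0.611% ± 0.102: Mir338 stood at 3442 ± 845 CPM and Mir219a-2, a driver of oligodendrocyte maturation, at 2665 ± 168 CPM. Its other members were at or near the floor, with Mir219a-1 at 5.43 ± 1.73 CPM, Mir3065 at 1.66 ± 2.04 CPM, and Mir219b and Mir219c at 0. The vascular and mesenchymal list took 4.48% ± 0.0323, with Mir126a first, Mir143 of smooth muscle at 8305 ± 1084 CPM, Mir221 at 7553 ± 3517 CPM and Mir222 at 3160 ± 2954 CPM. The microglia and leukocyte-enriched list took 0.800% ± 0.382, with Mir21a first, Mir342 at 2361 ± 1031 CPM, Mir150 of lymphocytes at 788 ± 50.02 CPM and Mir146 at 750 ± 68.9 CPM.

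The lists for blood and for tissue next to the hippocampus or elsewhere took small shares of the counts. Which cells these counts came from was not tested. The erythroid list took 0.0137% ± 0.000177 of the counts, with Mir451a at 88.0 ± 24.1 CPM, Mir144 at 33.1 ± 22.3 CPM, Mir486 at 15.9 ± 0.0238 CPM and Mir451b at 0. Mir486 shares a stretch of 20 bases with another hairpin, so it can lose reads to multimapping. Its level and the erythroid share can be too low. The choroid plexus and ependyma list took 0.264% ± 0.138. Mir34c, a miRNA of ciliated cells, was at 981 ± 870 CPM, Mir204, abundant in choroid plexus, at 917 ± 166 CPM, Mir1298 at 182 ± 66.0 CPM and Mir429 at 170 ± 123 CPM. The sensory and midline brain cluster took 0.0219% ± 0.0116, with Mir183 at 141 ± 80.8 CPM, Mir182 at 75.4 ± 34.4 CPM and Mir96 at 2.44 ± 0.943 CPM. The posterior Hox-linked list, typical of spinal cord and trunk, took 0.00416% ± 0.00206. Mir10a was at 27.7 ± 16.6 CPM, Mir10b at 9.63 ± 1.08 CPM, Mir196b at 2.54 ± 1.72 CPM and Mir615 at 1.55 ± 0.937 CPM; Mir196a-2 was at 0.221 ± 0.313 CPM and Mir196a-1 at 0.

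The imprinted Dlk1-Dio3 locus, whose miRNAs are made from the maternal chromosome, was broadly active. Of its 53 listed genes, which span chromosome 12 from 109563692 to 110278129, 49 reached 1 CPM in both libraries. Together they took 11.3% ± 1.42 of the counts. Mir127 led, followed by Mir411 at 9333 ± 2063 CPM, Mir487b at 8508 ± 1290 CPM and Mir770, in an exon of Meg3, at 7652 ± 2204 CPM. The list of the other large imprinted cluster took 0.0814% ± 0.00255. Of its 44 genes in the files, 43 lie in Sfmbt2 on chromosome 2, and the other, Mir669n on chromosome 3, had no count. Of the 43, 8 reached 1 CPM in both libraries and 29 had no count. However, 18 of the 43 are same-named copies and 42 share a stretch of 20 bases with another hairpin, so their reads can be lost to multimapping. Of the 53 Dlk1-Dio3 genes, 0 are same-named copies and 7 share such a stretch, so multimapping can lower levels at both loci and they were not compared. Mir467d was at 298 ± 59.4 CPM, Mir467e at 214 ± 29.8 CPM, Mir669c at 196 ± 18.5 CPM and Mir669o at 62.7 ± 22.3 CPM.

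Among the other families, miR-30 took 1.72% ± 0.113 of the counts. Mir30d was at 6929 ± 242 CPM, Mir30a at 5324 ± 379 CPM and Mir30e at 4478 ± 443 CPM, while Mir30c-2, Mir30b and Mir30c-1 lay between 110.1 and 169 CPM. The miR-181 family took 0.465% ± 0.00597, with Mir181c at 1888 ± 112 CPM, Mir181d at 1476 ± 2.83 CPM, Mir181b-2 at 685 ± 112 CPM and Mir181a-1 at 572 ± 47.4 CPM. Mir181a-2 was at 18.9 ± 14.0 CPM and Mir181b-1 at 7.41 ± 4.84 CPM. The miR-17-92 and paralogous clusters, known for promoting proliferation, took 0.237% ± 0.0173. Mir93 was at 1054 ± 142 CPM, Mir92-1 at 362 ± 86.6 CPM, Mir17 at 342 ± 13.5 CPM and Mir106b at 337 ± 37.2 CPM.

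Some genes that exist as same-named copies held few counts, and others were abundant. Copies such as Mir124a-1, Mir124a-2 and Mir124a-3 carry the same mature sequence, and the files set reads that fit several places apart as a separate total, outside the gene counts. The 3 copies of Mir124a, the best known neuronal miRNA, held 24 counts in sum over both libraries, and the 3 copies of Mir9, known from neural progenitors, held 640. By contrast, Mir128-1, at 12708 CPM, Mir138-1 and Mir219a-2 are such copies too. The arms were not told apart, so their counts do not show that reads of the shared mature sequence were kept. Of the 141 copies in the files, 45 (31.9%) reached 1 CPM in both libraries, against 20.3% of all genes, and 82 (58.2%) had no count, against 66.7% of all genes. All genes are not a matched comparison, so these shares do not show that the copies kept their reads. Together the copies took 3.53% of the counts. Reads set aside as multimapping numbered 1.20 per counted read in replicate 1 and 1.29 in replicate 2. The levels of these copies are therefore uncertain and can be too low, and so are the shares of the lists they belong to. Copies made up 11 of 18 activity- and synapse-linked, 11 of 30 neuron-enriched, 9 of 15 progenitor and astrocyte-enriched, 6 of 12 let-7, 4 of 6 miR-181 and 18 of 44 Sfmbt2 genes. They also made up 4 of 15 miR-17-92 genes, 2 of 6 in the oligodendrocyte, Hox-linked and miR-30 lists, 2 of 11 vascular, 2 of 12 ageing and 6 of 39 other-tissue genes. Genes without such names can lose reads too: 1084 genes in the files share a stretch of 20 bases with another hairpin.

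The libraries ranked the genes alike but differed far beyond counting error. Across 541 genes, Pearson's r of log2(CPM + 1) was 0.978 and Spearman's rho was 0.957; genes are not independent replicates. The chi-square over its degrees of freedom against Poisson sampling was 572, so these were not counts of 1 library deposited as 2. The libraries also differed in the fate of their reads: 29.0% were unmapped in replicate 1 and 11.2% in replicate 2, and 36.2% and 47.9% were multimapping. The common biological coefficient of variation from edgeR was 38.9% (34.0 to 44.8, bootstrap over genes). The median absolute log2 ratio was 0.51 over all 495 genes tested and 0.41 over the 96 genes with a mean of 1000 CPM or more.

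Individual miRNAs differed up to 47.3-fold between the libraries, and more were lower than higher in replicate 2. Mir26a-1 (chromosome 9, 119031796 to 119031885, in an intron of Ctdspl) had 648 counts in replicate 1, or 287 CPM (95% Poisson interval 266 to 310.2), and 27 counts in replicate 2, or 5.97 CPM (3.94 to 8.69). It is a same-named copy, as are Mir129-1 and Mir9-1, so these levels are uncertain. Mir1247 (chromosome 12, 110278048 to 110278129, in an exon of Dio3os) had 312 CPM (289 to 336) against 12.8 CPM (9.74 to 16.6), 24.1-fold lower in replicate 2. Mir301 (chromosome 11, 87113004 to 87113089, in an intron of Ska2) went the other way, from 49.6 CPM (40.9 to 59.7) to 615 CPM (592 to 638), 12.3-fold higher. Mir195a, a miRNA that limits cell cycle genes, was 5.48-fold higher in replicate 2, and Mir99b was 2.55-fold higher. Of the genes lower in replicate 2, Mir543 was 5.67-fold, Mir222 4.90-fold, Mir200c 4.72-fold, Mir874 4.64-fold, Mir129-1 4.38-fold and Mir34c 4.36-fold lower. Mir200a (3.45-fold) and the unnamed gene Gm24270 (3.38-fold) were lower as well. Mir193a was 3.62-fold, Mir9-1 3.11-fold, Mir122 2.91-fold, Mir144 2.80-fold, Mir539 2.65-fold, Mir1843b 2.56-fold and Mir504 2.48-fold higher.

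In all, 87 of 495 tested genes were called by the exact binomial test (Benjamini-Hochberg adjusted p under 0.05 and 2-fold or more), 19 higher and 68 lower in replicate 2. With edgeR's TMM factors the split was 26 higher and 51 lower, and with DESeq2 size factors 27 and 48, because those scalings raise every log2 ratio by 0.12 and 0.19. Of the 96 genes with a mean of 1000 CPM or more, 15 were called, 2 higher and 13 lower. The test compares the reads of these 2 libraries, 1 per sample, and has no replicate check. When edgeR's exactTest took the spread between the libraries as the error, 3 genes remained, namely Mir26a-1, Mir1247 and Mir301.

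**Figure D2:**
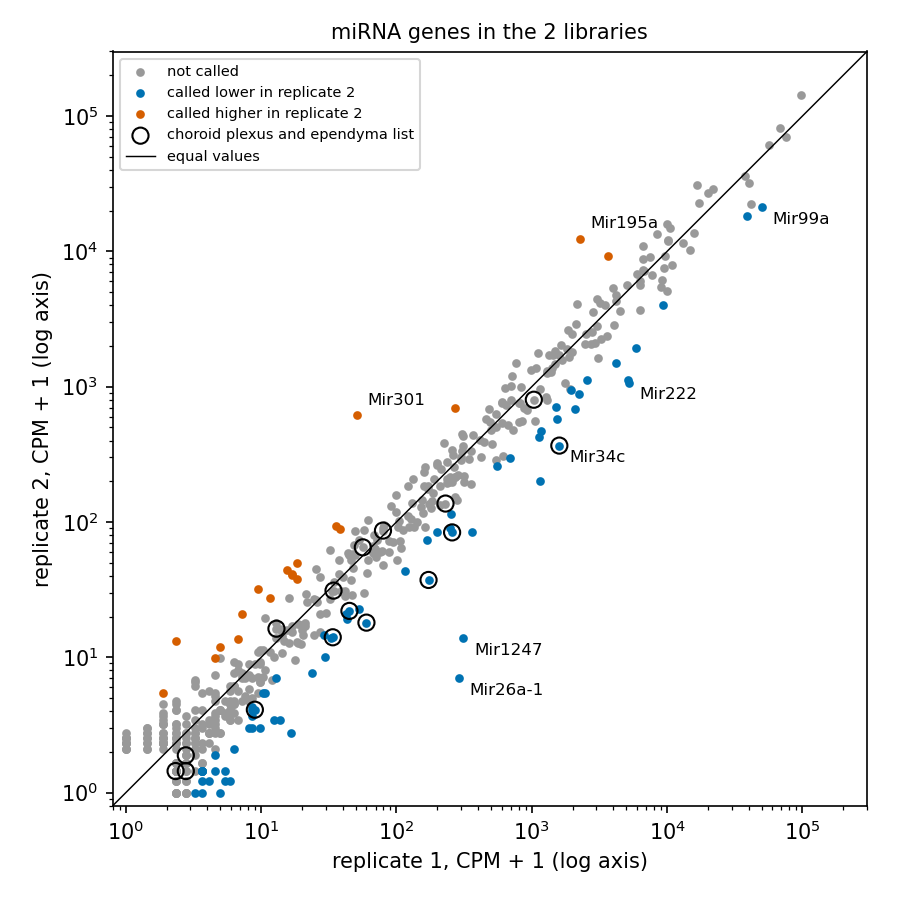
CPM + 1 in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, for 541 miRNA genes at 1 CPM or more in at least 1 library, with the line of equal values. Blue points are the genes called lower in replicate 2, orange points those called higher, grey points those not called, and black rings the choroid plexus and ependyma list, of which 7 members were called lower.

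The choroid plexus and ependyma list stood apart most clearly between the libraries. Of its 15 tested members, 7 were called lower in replicate 2 and 0 higher. Mir34c stood at 1597 CPM in replicate 1 and 366 CPM in replicate 2, and Mir429 at 257 and 82.7 CPM. Mir200c stood at 172 and 36.3 CPM, and Mir200a at 59.0 and 17.0 CPM. Mir204 was not called, at 1034 and 800 CPM. The members did not all fall: Mir200b, in the same Ttll10 intron cluster as Mir200a and Mir429, had a log2 ratio of 0.12 (78.5 and 85.4 CPM), Mir449a of 0.20 and Mir764 of 0.33. The list's median log2 ratio (replicate 2 over replicate 1) was -1.06, at percentile 0.045 of 10000 random lists matched on expression. The percentile describes these libraries, and 18 lists were looked at. Members of 1 cluster or host gene, such as those in Ttll10 or Htr2c, may not be independent, whereas the random lists drew single genes.

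For 3 other lists the median lay above the central 95% of matched random lists. The neural progenitor and astrocyte-enriched list had a median of 0.32 (percentile 98.7), with 2 of 15 tested members called higher (Mir193a and Mir9-1) and 2 lower (Mir26a-1 and Mir31). The ageing list had a median of 0.35 (percentile 98.5), with Mir144 called higher and Mir21a, known from activated glia and fibrosis, called lower at 1945 against 5880 CPM. These lists share the miR-29 genes, of which Mir29a had a log2 ratio of 0.91 and Mir29c of 0.92. The posterior Hox-linked list had a median of 1.18 over 4 members (percentile 99.2), of which Mir10a was called higher, at 39.4 against 16.0 CPM, and the others had at most 47 counts in either library. Without its most changed member that list had a median of 1.07 (percentile 95.1), inside the central range. For the first and second of these lists, a correction for hairpin GC content brought the percentiles to 92.3 and 90.9.

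The remaining 14 lists had medians inside the central 95% of their random lists. The neuron-enriched median was -0.18 (percentile 21.6), with 3 of 28 members called lower, Mir132 among them, and 0 higher. The activity- and synapse-linked median was -0.32 (15.5), with 3 of 16 lower and 0 higher. The Dlk1-Dio3 median was -0.19 (21.9), with 7 of 49 lower and 2 higher. The oligodendrocyte-enriched median was -0.59 (24.2), with 1 of 4 lower, Mir3065, at 7 and 1 counts. The microglia and leukocyte-enriched median was -0.28 (27.1), with 2 of 8 lower. The vascular and mesenchymal median was 0.10 (71.8), with Mir222 lower among 6 members. The erythroid median was -0.01 (67.1), with Mir144 higher among 3. The sensory and midline median was -0.97 (7.21), with Mir183 lower among 3, and the other-tissue median -0.02 (69.9), with Mir122 higher among 7. The let-7 median was 0.07 (70.4) and the miR-30 median 0.17 (83.2), with 0 of 12 and 0 of 6 called. The miR-181 median was -0.06 (61.6), with 1 of 6 higher and 1 lower, the miR-17-92 median 0.22 (93.5), with 0 of 11 called, and the Sfmbt2 median -0.48 (19.5), with 1 of 9 lower. With DESeq2 size factors the neuron-enriched, Dlk1-Dio3, erythroid, miR-181 and other-tissue medians turned positive, and with TMM factors the last 3 of these did. After the correction for hairpin GC content all of these medians were positive, as was the microglia and leukocyte-enriched median (0.008). They stayed inside the central range of their random lists. That correction also centres the log2 ratios of all tested genes, whose median was -0.19 before, on a mean of 0. The changes of sign thus cannot be credited to GC content. In each of the 18 lists the calls adjusted over the list alone numbered the same as those adjusted over all genes tested.

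**Figure D3:**
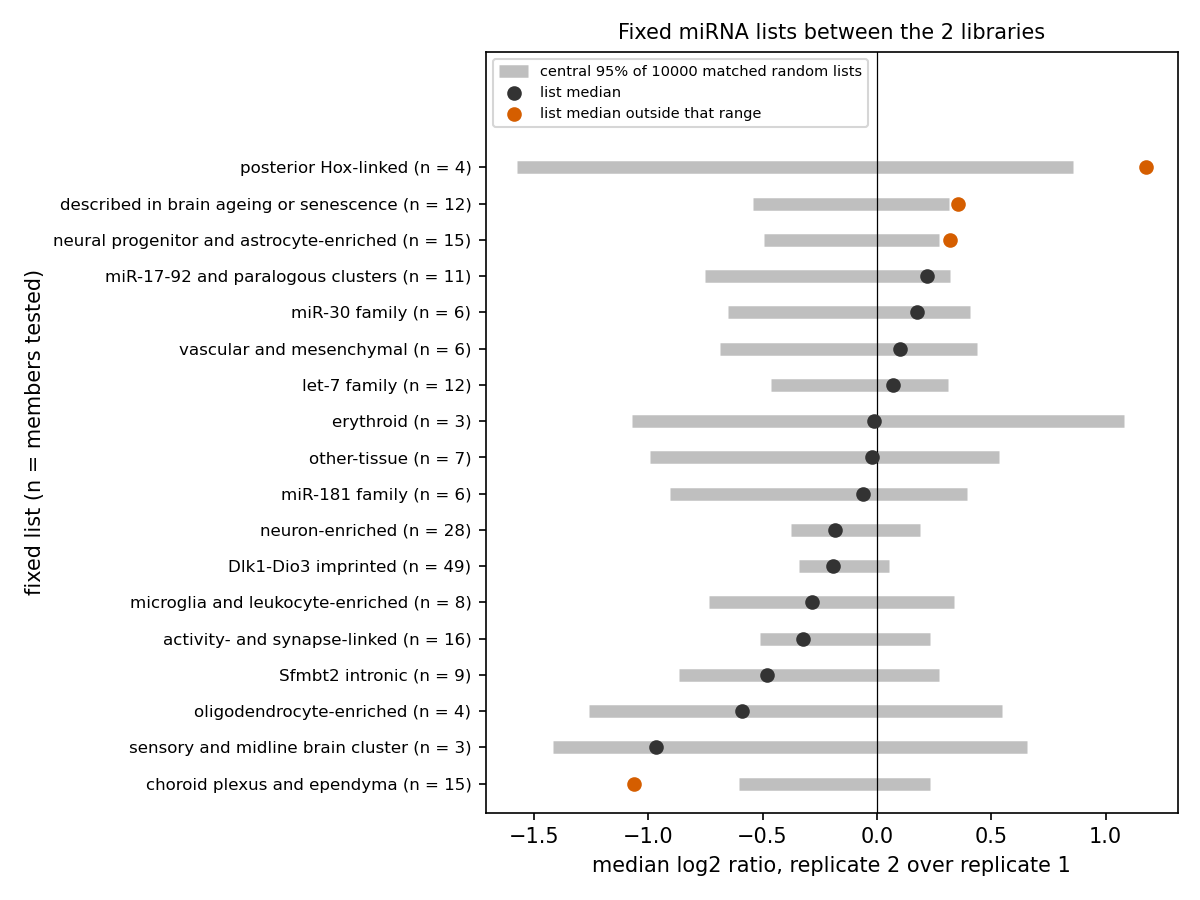
Median log2 ratio, replicate 2 over replicate 1 (x axis), of the 18 fixed lists (y axis, n tested members), as points over the central 95% of 10000 matched random lists (grey bars). Orange points lie outside their bar: the choroid plexus and ependyma list at -1.06, and the astrocyte, ageing and Hox-linked lists at 0.32, 0.35 and 1.18.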

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

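All tests in this part were chosen after the patterns were seen; for hairpin GC content, what each outcome would mean was written before the outcome was known, and for the others after. No biological explanation was tested for the antisense counts, which come first.

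The antisense column, which no comparison used, gave 41 genes more antisense than sense counts. The 5 with the most had no sense count, and their sums lay above the limit that a count of 0 allows. Over both libraries Mir126b had 180614 antisense counts, Gm25927 167395, Gm24083 97212, Mir30f 31059 and Gm25301 22657. For these 5, in each library, the number equalled the sense counts of the gene on the other strand, which were Mir126a, Mirlet7e, Mir191, Mir30e and Mir378a. They are the same reads listed again and add no signal. Outside such pairs the antisense column held 66 counts in replicate 1 and 119 in replicate 2. In replicate 1, Mir3083 had 20, Mir5620 17, Mir708 7 and Mir7240 6 antisense counts. In replicate 2, Mir3083 had 36, Mir5620 17, Mir7654 9, Mir8105 7, Mir3105 6, Mir34b 6 and Mir708 5.

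The first pattern weighed is the low count at the same-named copies of Mir124a and Mir9. Among the neuron-enriched and the progenitor and astrocyte-enriched genes, the 20 same-named copies lay -3.65 log2 units from the 25 other members in mean log2(CPM + 1) (two-sided permutation p = 0.001), but they include the 6 Mir124a and Mir9 copies that prompted the test. Without these 6, the other 14 copies lay -1.73 log2 units from the same 25 members (two-sided permutation p = 0.0745). That comparison concerns other genes, so it cannot decide the cause for Mir124a and Mir9. Reads that fit several copies are kept outside the gene counts, so such reads are lost to Mir124a and Mir9, but their number is not known. How far this loss accounts for their low counts stays open. Low expression of these miRNAs in the tissue stays open for each of them, because the 1.26 multimapping reads per counted read carry no gene name.

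The second pattern is the choroid plexus and ependyma list, lower in replicate 2. Removing a quadratic fit on hairpin GC content left its median at -0.84, at percentile 0.03 of matched random lists. That argues against the GC content of the whole hairpin as the whole cause. The GC content of the mature RNA that was sequenced was not measured, so it stays open. Less choroid plexus or ependyma in the dissection of replicate 2 stays open: the 7 Trpm3, Trpm1 and Htr2c members had a median of -0.76, the 5 miR-200 members -1.63 and the 3 miR-34 and miR-449 members -1.06, while Mir200b (0.12), Mir449a (0.20) and Mir764 (0.33) did not fall. Against random lists of their own size, only the miR-200 members lay under the 2.5th percentile (0.105, against 7.18 and 4.16 for the others), and all 3 are parts of a list picked for being low. Mir204 differed by 1.29-fold, and with 1 library per sample, and unmapped shares of 29.0% and 11.2%, dissection and library preparation cannot be told apart.

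The third pattern is the set of differences between the libraries. Counting error is excluded for the abundant genes, since 15 of the 96 genes with a mean of 1000 CPM or more were called at 2-fold. Hairpin GC content correlated with the log2 ratio across the 495 tested genes at r = -0.13 (permutation p = 0.00358, rho -0.11). It held 1.68% of the variance (95% bootstrap interval 0.161 to 4.77), too little to be the main cause. The GC content of the mature RNA that was sequenced was not measured, so its part stays open. The first base of the mature miRNA, a feature that adapter ligation can favour, held 4.95% of the variance over 79 abundant genes (1.02 to 22.8; permutation p = 0.275), but its part stays open, since the counts sum both arms and the dominant arm was not checked. Animal, dissection and library preparation remain open and untested: the labels give no batch, while unmapped reads made up 29.0% in replicate 1 and 11.2% in replicate 2, and multimapping reads 36.2% and 47.9%.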

How the results depend on the processing

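The correction for GC content, the removal of same-named copies and that of the most changed member were chosen after the data were seen. Of the 446 detected genes, the count rose to 734 with at least 1 count in either library, and other filters kept it within 1.5 times. The top 10 share was 57.0% in the unstranded column and 52.8% to 53.6% in single libraries. The correlation was 0.9835 with a pseudocount of 5 CPM and 0.969 for genes at 10 CPM in both libraries, just outside its bootstrap interval of 0.973 to 0.9827; the cause was not tested. The coefficient of variation stayed within its interval under all 5 alternatives.

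The 87 called genes became 53 (39 lower) at a mean of 10 CPM or more, where fewer genes were tested, and 141 (40 higher, 101 lower) at 1.5-fold. With edgeR's exactTest they became 3 (1 higher, 2 lower), with 26 genes at an unadjusted p under 0.05, because the spread between the libraries was then the error. The TMM and DESeq2 calls shared 70 and 67 genes with the main calls. The choroid plexus and ependyma median ran from -1.06 to -0.84 and stayed under the 2.5th percentile in all 5 alternatives. The GC correction moved the astrocyte median to 0.43 (percentile 92.3) and the ageing median to 0.45 (90.9), inside the random range although the medians rose, since the fit also moved the random lists. Without its most changed member the Hox-linked median was 1.07 (95.1), over 3 genes. The neuron-enriched excess over other-tissue genes kept its p under all 6 alternatives, from 6.90 to 10.7 log2 units.

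Of the 121 gene levels and list shares, 30 moved beyond their spread in the unstranded column, where 11 of 103 named genes, Mir126a, Mirlet7e and Mir191 among them, fell to 0 because a gene on the other strand overlaps them. Of the other 14 list medians, 4 moved beyond their spread with the GC correction and 3 with DESeq2 size factors, and with TMM factors 1 of 117 gene levels and medians did. The GC correction also centres the log2 ratios of all tested genes on a mean of 0, so such moves are not those of GC content alone. No paired analysis was possible because there is 1 group. No library could be left out of a comparison between the 2 libraries. Depth limits what can be read of genes near the floors of 1.33 CPM in replicate 1 and 0.664 CPM in replicate 2.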

Other observations

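Tests in this part were chosen after the data were seen, and the genes named here lie partly outside the rule for named genes. Several abundant genes belonged to none of the fixed lists. Besides Mir139, Mir744 and Mir99a, these included Mir330 in an exon of Eml2 at 9445 ± 342 CPM, Mir23a at 8760 ± 3041 CPM, Mir652 in an intron of Tmem164 at 7705 ± 1494 CPM, Mir92b at 7225 ± 2467 CPM and Mir100 at 6664 ± 3737 CPM.

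Neighbouring genes of a cluster stood at similar levels in some cases and at very different levels in others. The ratios below are those of counted reads, which adapter ligation can shift between miRNAs. Mir183 was 1.87 times as abundant as Mir182, and Mir99b stood at 0.499 of the level of Mir125a. Mir132 was 69.1 times as abundant as Mir212, whose hairpin starts 294 bp away. Mir29a was 541 times as abundant as Mir29b-1, a same-named copy whose level is uncertain. Mir143 was 31.8 times as abundant as Mir145a, and Mir23a 50.6 times as abundant as Mir27a.

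Mir99a and Mir100, on chromosomes 16 and 9, had log2 ratios of -1.25 and -1.21 between the libraries, whereas Mir99b, of the same family on chromosome 17, had 1.35. Of the called genes, Mir132 had a log2 ratio of -1.09 and its neighbour Mir212 had -0.93, while Mir195a had 2.45 and its neighbour Mir497 had 0.51. Over 96 neighbouring pairs on 1 strand within 10000 bp at 10 CPM or more, the median absolute difference in log2 ratio was 0.60, against 0.67 when the ratios were shuffled among these genes (one-sided permutation p = 0.176). In 27 of the pairs the log2 ratios lay 1 or more apart.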
